A study of Mus musculus with 62 samples.

How the data were processed

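Quadriceps muscle from 62 male mice was profiled by sequencing of poly-A RNA. The mice formed a full factorial of voluntary wheel running, nicotinamide riboside (NR, a vitamin B3 form that cells convert to NAD) and pterostilbene (PT, a plant stilbenoid related to resveratrol), with 8 groups of 7 or 8 animals. The series title gives the route of NR as intravenous, whereas the sample labels state only its presence or absence. Per the labels' protocols, RNA was extracted with TRIzol and columns with DNase digestion, and libraries were made with a stranded poly-A kit from Illumina. The labels give each library a cohort, a day and a time of termination, 1 of 3 purification pools, a body weight change whose unit is not stated and an RNA integrity number (RIN) of 8.6 to 10.

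The deposited table holds whole-number read counts per gene, not normalized. The authors aligned reads with STAR 2.7.3a, counted them with featureCounts 2.0.0 and used the mouse build mm10, per the submitters' processing notes. The strand setting of the counting and the annotation release are not given in the sources used here, so counts of genes that overlap on opposite strands, and of near-identical gene copies, are uncertain. The table covers 55487 gene identifiers, of which 55394 (99.8%) were matched to symbols through GENCODE M21. The chromosome was the same for 100% of the matched genes and the start and end for 87.4%, so coordinates are printed as deposited, in mm10. Each value column matched 1 sample title.

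Genes were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Low counts were filtered with filterByExpr (minimum count 10, minimum total 15), which left 14549 genes. Libraries were scaled by TMM, and a quasi-likelihood F test with robust dispersion was fitted with the 8 groups, the 8 days of termination and the time of termination (morning or noon). This left 46 residual degrees of freedom, and the biological coefficient of variation was 14%. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, and a gene was called at an adjusted p below 0.05. Levels are in CPM, the usual library-size-scaled counts, with TMM-scaled library sizes, and fold changes come from the fitted model. The design, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined.

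For each main effect the rule named the 12 largest rises and 12 largest falls among called genes with a mean of at least 1 CPM, skipping predicted genes, or the 5 smallest p-values where fewer than 5 genes were called. For each interaction and each effect within a subset it named up to 5 called genes with the smallest p, for each described list up to 4 members with the smallest p, and in addition 14 genes of NAD metabolism, fibre type and exercise. Some genes that the rule named are left out of the text because they are withheld for evaluation. The 27 gene lists cover energy metabolism, NAD, insulin signalling, sarcomeres, exercise regulators, the circadian clock, extracellular matrix, stress responses, interferon, atrophy, lipogenesis, regeneration, and markers of 8 other cell types. Lists were tested with camera on voom log2 CPM with a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 27 lists of a contrast by the Benjamini-Hochberg method. Members were also counted with p-values adjusted over the list alone. Camera compares a list with the other genes, whereas fry asks whether the list's own genes moved one way. The extracellular matrix and fibroblast lists share 4 genes, Col1a1, Col3a1, Fbn1 and Lum, and Me1, Klf15, Trib3 and Des each stand in 2 lists.

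The pipeline was tested on simulated counts with 50 changed genes at each fold size. For the running comparison over 14464 genes, edgeR recovered 36% of 1.1-fold, 74% of 1.25-fold, 100% of 1.5-fold and 100% of 2-fold changes with 9 false calls. DESeq2 1.42.0 recovered 40%, 76%, 100% and 100% with 13 false calls. The simulation drew each animal independently and held no differences between days or times of termination. Changed genes were drawn only from those above 1 CPM on average, so the rates do not cover genes with lower counts.

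Totals ranged from 5.64 to 30.8 M counts per library, with a median of 16.1 M. Mitochondrially encoded genes took 8.52 to 16.06% of counts and the 10 most abundant genes 24.75 to 44.7%. Reads without molecular identifiers are not independent molecules. The lowest chi-square per gene between replicates of 1 group was 5.23, above the value near 1 that sampling noise alone gives. A summed measure of 11 ribosomal-RNA-like genes, and the limit of 5 times its median above which 4 libraries lie, were chosen after the data were examined. RIN, library size and this measure did not differ by running, NR or PT in permutation tests with 100000 resamples (lowest adjusted p = 0.72).

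Within each day all running mice were labelled with 1 time of termination and all other mice with the other. Running was therefore shared by the animals of a session, and the labels define 16 sessions of at most 4 animals. This was noticed after the data were examined, so the design above was kept, and 3 further fits were added, with the session as a random block in limma, with the session as a fixed block (which leaves running without an estimate) and on counts summed per session. Removal of days 2 and 3, of 1 library rich in ribosomal-like reads and of all 4 such libraries was also added after the data were examined. Alternatives chosen beforehand were DESeq2, RLE scaling, other filters, other covariates, the replicate number as a block, each cohort alone and each day left out.

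Regroupings of the samples were refitted to ask how often other splits call as many genes. For supplements, 40 regroupings were drawn. For running and time, the first regroupings exchanged single animals within days, and they were replaced, after their results were seen, by exchange of whole days, which keeps the sessions intact. For running their number was then raised from 40 to 75, because 40 draws with another seed put the endothelial result on the other side of the limit. Tests of the endothelial list against RIN and against nerve markers were first planned as a weighed pattern and are given only as values. The numbers of replicates carry no stated pairing. No sample was left out of the main tests.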

Results

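Poly-A RNA from the quadriceps of 62 male mice was counted per gene to ask how running, NR and PT, alone and in combination, changed muscle gene expression. There were 30 running and 32 non-running mice, 31 with and 31 without NR, and 32 with and 30 without PT. Each group held 8 animals, 1 for each of 8 termination days, except running with NR alone and running with neither supplement, which held 7. Median totals per group lay between 14.1 M counts in runners with both supplements and 20.18 M in runners with PT alone. Of 14549 genes tested, 2035 passed the test for running, 3 for NR and 0 for PT.

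Running was the factor with the most called genes, and its changes were small. Of 2035 called genes, 1223 rose and 812 fell in 30 runners against 32 non-runners, with a median change of 1.12-fold. The balance differed between fits, with 1104 up and 1039 down with RLE scaling and 1213 up and 1168 down with DESeq2. Only 55 of them moved by more than 1.5-fold and 7 by more than 2-fold. The largest rise among named genes was that of Myl2, the slow myosin regulatory light chain, at 3.72 ± 5.51 CPM in runners and 1.41 ± 1.63 CPM in non-runners (SD), a log2 change of 1.24 ± 0.42 (SE). The largest fall was that of Sln, sarcolipin, an inhibitor of the sarcoplasmic calcium pump (chromosome 9, 53850164 to 53854560), from 3.52 ± 2.45 to 1.17 ± 0.825 CPM, a log2 change of -1.55 ± 0.24 (edgeR adjusted p = 2.54e-05).

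Other large rises included Bdh1, a mitochondrial enzyme of ketone body oxidation, with a log2 change of 0.98 ± 0.25 (SE), Actc1, cardiac alpha-actin, with 0.77 ± 0.12, and Mb, myoglobin, with 0.67 ± 0.15. Myh1, the fast oxidative-glycolytic myosin IIx, rose by 0.67 ± 0.14, from 2880 to 4670 CPM. The remaining named rises were H2-Q10 at 0.95, Col28a1 at 0.74, the cartilage matrix protein gene Chad at 0.73, Slc15a5 at 0.69, Inpp5j at 0.69, Smtnl1 at 0.68 and Masp1 at 0.65. Among falls, Cdkn1a, the cell cycle inhibitor p21, changed by -0.66 ± 0.12 and Aldh3a1, an aldehyde dehydrogenase, by -1.09 ± 0.22. Fkbp5, a gene induced by glucocorticoids, changed by -0.44 ± 0.12 and Kl, klotho, by -0.54 ± 0.13. Rasd2 changed by -0.41 ± 0.06, in the same direction in 29 of 30 runner and non-runner pairs of 1 day and supplement arm. The other named falls were Prss55 at -0.55, Odf3l2 at -0.54, C1qtnf4 at -0.47, Uts2r at -0.42, Rrad at -0.41 and Adcy1 at -0.41.

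Some genes of mitochondrial energy metabolism rose with running, and no member of the 4 lists below fell. Of 79 nuclear-encoded subunits of oxidative phosphorylation, 50 rose and none fell (66 rose adjusted over the list alone), with a median log2 change of 0.14. Examples were Cox7a1 at 0.34 ± 0.06 (SE), Atp5b at 0.20 ± 0.04, Uqcrc1 at 0.22 ± 0.04 and Ndufa10 at 0.21 ± 0.04. Of 8 tested mitochondrially encoded subunits 7 rose, led by mt-Co1 at 0.28 ± 0.05 and mt-Cytb at 0.23 ± 0.05. Of 18 genes of the TCA cycle 16 rose, among them Pdha1 at 0.25 ± 0.04, Dlat at 0.22, Cs (citrate synthase) at 0.16 and Mdh2 at 0.22. Of 30 genes of fatty acid oxidation 10 rose, among them Acads at 0.26, Hadh at 0.21, Cpt2 at 0.18 and Lpl at 0.29. Camera called these 4 lists with the preset correlation (adjusted p = 4.9e-21, 9.6e-06, 1.4e-13 and 1.5e-05). None of the calls held with an estimated correlation (adjusted p = 0.29, 0.22, 0.2 and 0.41 with an estimated correlation), whereas fry gave 0.0037, 0.0014, 0.00043 and 0.033.

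All 18 endothelial markers rose with running, with a median log2 change of 0.25. Cdh5, which encodes VE-cadherin (chromosome 8, 104101625 to 104144511), rose from 72.7 ± 5.6 to 93 ± 16.6 CPM (SD), a log2 change of 0.35 ± 0.04 (SE). Sox17, an endothelial transcription factor, rose by 0.40 ± 0.06, the apelin receptor gene Aplnr by 0.63 ± 0.10 and Tie1 by 0.30 ± 0.05. This was the only 1 of 27 lists called for running with both the preset and the estimated correlation (adjusted p = 2e-17, and adjusted p = 0.025 with an estimated correlation).

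Of 35 extracellular matrix genes 17 rose and none fell (22 adjusted over the list alone), including the basement membrane collagens Col4a1 at 0.37 ± 0.07 and Col4a2 at 0.32 ± 0.06 (SE), with Bgn at 0.33 and Col15a1 at 0.31 (camera adjusted p = 6.1e-13, and adjusted p = 0.22 with an estimated correlation). Of 20 interferon response genes 4 rose, namely Rsad2 at 0.59, Oas2 at 0.38, Ifit3 at 0.30 and Bst2 at 0.28 (camera adjusted p = 0.00086, and adjusted p = 0.39 with an estimated correlation). Among markers of other cell types, 2 of 17 macrophage and neutrophil genes rose (Cd68 at 0.36 and Ptprc at 0.26), with camera adjusted p = 0.00013 and adjusted p = 0.39 with an estimated correlation. Of 15 fibroblast genes 2 rose (Lum at 0.33 and Col3a1 at 0.39), with camera adjusted p = 0.0012 and adjusted p = 0.39 with an estimated correlation. Of 6 lymphocyte genes 1 rose (camera adjusted p = 0.027, and adjusted p = 0.36 with an estimated correlation). In the smooth muscle and pericyte list of 12, the pericyte genes Rgs5 and Pdgfrb rose by 0.23 each and Cspg4 by 0.17, while Acta2 changed by -0.21 (camera adjusted p = 0.2). Of 14 adipocyte genes 2 rose (camera adjusted p = 0.11), 0 of 6 erythrocyte genes passed the test in edgeR (camera adjusted p = 0.29), and the Schwann cell and nerve list had a camera adjusted p of 0.12.

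**Figure D1:**
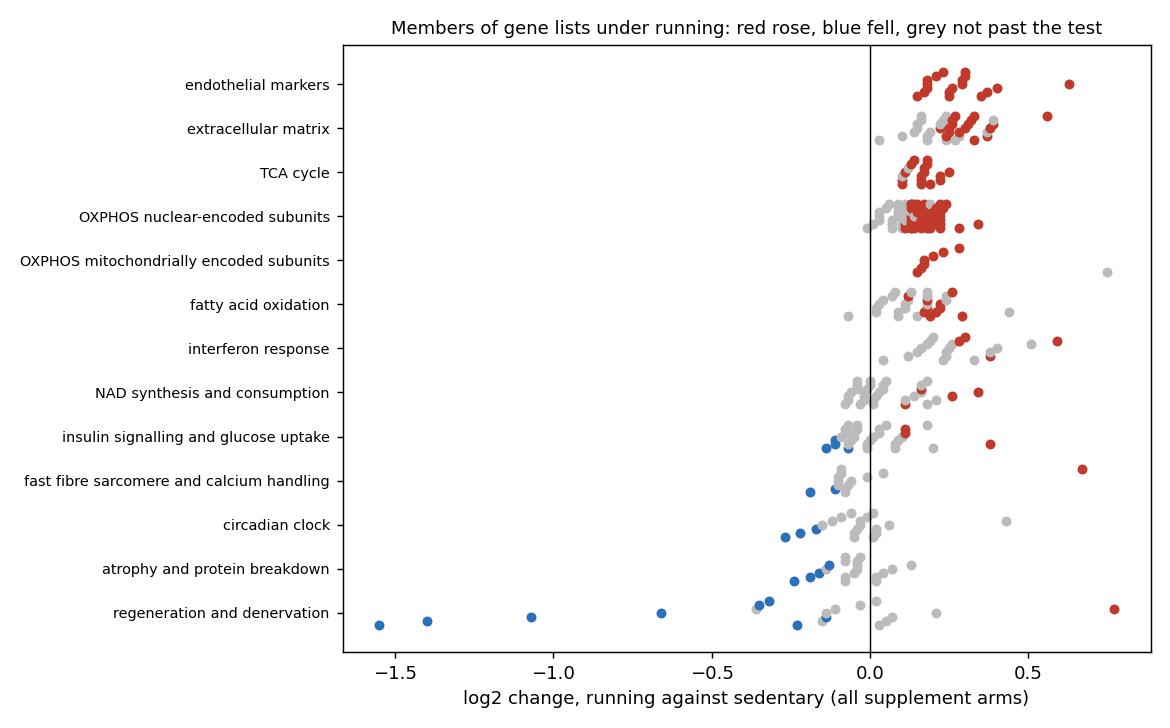
Each point is 1 gene of a list, placed by its log2 change between 30 running and 32 non-running mice on the horizontal axis, with lists as lines on the vertical axis. Red genes rose, blue genes fell and grey genes did not pass the edgeR test; all 18 endothelial markers lie above 0.

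Called genes went both ways in the regeneration and fast fibre lists, and in a single direction in each of the atrophy, slow fibre, exercise and clock lists. In the regeneration and denervation list of 19, 8 genes fell, including Sln, Cdkn1a and Myod1 (-0.32 ± 0.06, SE), and Actc1 rose (camera adjusted p = 0.00058, and adjusted p = 0.076 with an estimated correlation). Of 19 atrophy genes 4 fell, among them Trim63, a muscle ubiquitin ligase, at -0.19 ± 0.04 and Mstn, myostatin, at -0.24 ± 0.08, with Bnip3 at -0.13 and Eif4ebp1 at -0.16 (camera adjusted p = 0.0016, and adjusted p = 0.2 with an estimated correlation). Of 14 fast fibre genes Actn3 changed by -0.19 ± 0.04 and Atp2a1 by -0.11 ± 0.03, whereas Myh1 rose (camera adjusted p = 0.00077, and adjusted p = 0.39 with an estimated correlation). Of 14 slow fibre genes Myl2 and Tpm3 (0.22) rose (camera adjusted p = 0.12). The slow myosin gene Myh7 had a log2 change of 1.17 ± 0.50 (adjusted p = 0.106), Myh2 0.50 ± 0.25 (adjusted p = 0.182) and Myh4 -0.10 ± 0.04 (adjusted p = 0.0939). Of 29 exercise regulators Ppargc1a, the coactivator PGC-1alpha, rose by 0.20 ± 0.05 (adjusted p = 0.00283) and Fndc5 by 0.29 ± 0.09 (camera adjusted p = 0.22 for the list). Of 19 clock genes Cry1, Rora and Nfil3 fell by 0.22, 0.17 and 0.27 on the log2 scale (camera adjusted p = 0.022, and adjusted p = 0.2 with an estimated correlation).

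In NAD metabolism 4 of 32 genes rose with running and none fell. They were the mitochondrial sirtuins Sirt3 at 0.26 ± 0.05 (SE), Sirt5 at 0.16 and Sirt4 at 0.11, and the NAD-consuming ectoenzyme Cd38 at 0.34 ± 0.06 (camera adjusted p = 0.22). The synthesis genes Nampt, Nmrk1 and Nmrk2 had log2 changes of -0.03, -0.02 and -0.06, Nnmt 0.02 and Sirt1 0 (lowest adjusted p = 0.608). In insulin signalling and glucose uptake 3 of 30 genes rose, including Grb14 at 0.38 ± 0.09, an adaptor that inhibits the insulin receptor, and Inppl1 at 0.11, and 4 fell, including Grb10 at -0.14 and Rps6kb1 at -0.11 (camera adjusted p = 0.21). The glucose transporter gene Slc2a4 had a log2 change of -0.07 ± 0.03 (adjusted p = 0.0936), Hk2 0.10 (adjusted p = 0.198), Pdk4 0.44 ± 0.22 (adjusted p = 0.165) and Vegfa 0.10 (adjusted p = 0.224). Of 16 glycolysis genes 1 fell, Pygm at -0.09 (camera adjusted p = 0.26). Of 22 antioxidant genes 5 fell, including Gstm1 at -0.15, Me1 at -0.15 and Nqo1 at -0.20, and 2 rose, including Sod2 at 0.14 (camera adjusted p = 0.22). In the heat shock list the endoplasmic reticulum chaperone gene Hspa5 fell by 0.21 and Hspa8 by 0.18 on the log2 scale, while Hspa4l rose by 0.20 (camera adjusted p = 0.22). Of 18 genes of the mitochondrial stress response Atf4 changed by -0.11, Shmt2 by 0.13 and Lonp1 by 0.09 (camera adjusted p = 0.62). Of 16 lipogenesis genes Elovl5, Thrsp and Acly rose by 0.20, 0.35 and 0.23 and Me1 fell (camera adjusted p = 0.11).

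All running calls share 1 limit of the design, because running mice and non-running mice of a day were terminated in different sessions. On counts summed per session 1275 genes passed the test, 1141 of them shared. Of the 24 genes named for size 17 passed there, with Myl2, H2-Q10, Aldh3a1, Odf3l2, Fkbp5, Uts2r and Rrad not passing (Myl2 adjusted p = 0.0884). The count was 1036 without day 1 and 1189 without day 4. Without the 1 library richest in ribosomal-like reads 1144 genes rose and 1247 fell. Cohort 1 alone called 623 genes, of which 604 had the same sign in cohort 2 and 39 were called there, and cohort 2 alone called 63, all 63 with the same sign in cohort 1.

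NR lowered Nmrk2 and raised Atcayos, which lie on opposite strands of 1 locus. Nmrk2, a muscle kinase that phosphorylates NR in NAD synthesis (chromosome 10, 81198170 to 81202051), was at 41.4 ± 16.8 CPM in 31 mice with NR and 89.2 ± 34.3 CPM in 31 without (SD). Its log2 change was -1.11 ± 0.14 (SE, edgeR adjusted p = 4.19e-06), lower with NR in 28 of 30 pairs matched by day and the other factors. Atcayos is an antisense transcript whose gene (81194609 to 81209161) covers the whole 3882-base span of Nmrk2, introns included. It rose from 95.9 ± 10.2 to 117 ± 13.1 CPM, a log2 change of 0.28 ± 0.04 (adjusted p = 4.19e-06, 27 of 30 pairs). The third called gene was Myh8, perinatal myosin, which rose from 3.85 ± 0.863 to 5.01 ± 1.12 CPM, a log2 change of 0.37 ± 0.08 (adjusted p = 0.0386, 24 of 30 pairs). The next smallest p-values belonged to Castor2, a log2 change of 0.12 ± 0.03 (adjusted p = 0.131), and Mymk, the muscle fusion gene myomaker, 1.60 ± 0.37 at 0.44 against 0.15 CPM (adjusted p = 0.233).

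**Figure D2:**
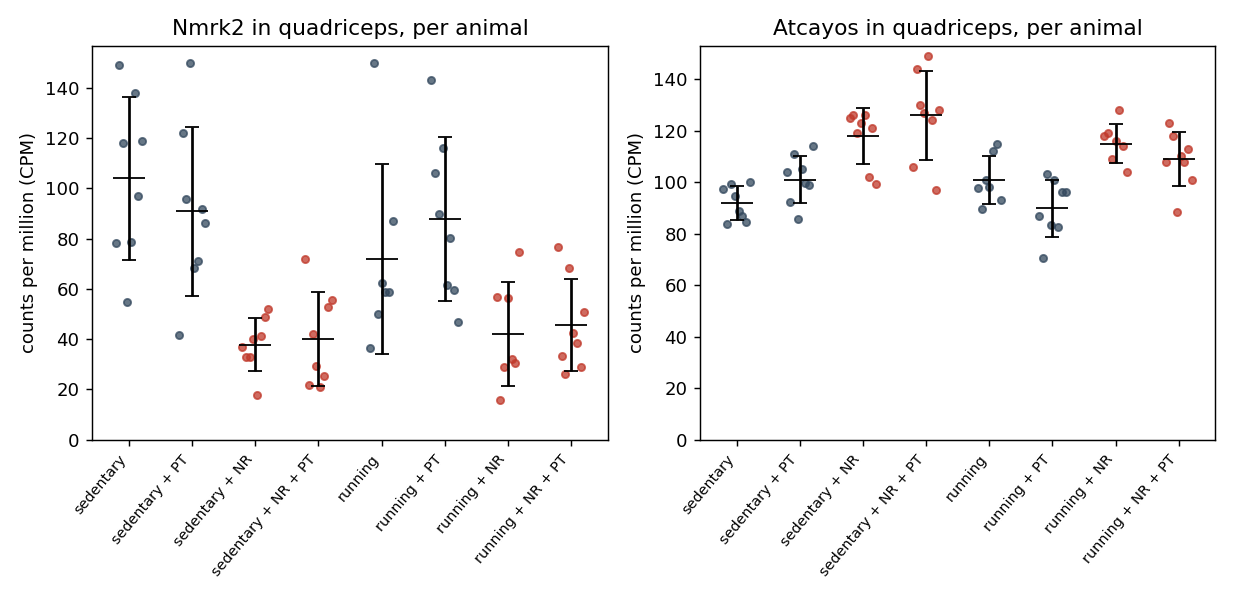
Each point is the level of Nmrk2 (left) or Atcayos (right) in 1 mouse, in CPM from 0 on the vertical axis, for the 8 groups on the horizontal axis, with red points for NR and bars for the mean and SD of 7 or 8 animals. Mean Nmrk2 lay between 37.8 and 45.7 CPM in the 4 NR groups and between 71.9 and 104 CPM in the others.

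The reads of Nmrk2, Atcayos and the neighbour Atcay (log2 change 0.33 ± 0.09, adjusted p = 0.411, NR main effect) cannot be separated with certainty, since the strand setting of the counting is not stated. The Nmrk2 change was -1.27 ± 0.22 in cohort 1 (adjusted p = 0.0771) and -0.90 ± 0.18 in cohort 2 (adjusted p = 0.159). Atcayos had 0.35 (adjusted p = 0.00135) and 0.23 (adjusted p = 0.159), and Myh8 kept its call in 2 of 8 fits that left out 1 day (adjusted p from 0.00759 to 0.573). NR effects were estimated within sessions, and 3 genes were called with the session as a fixed block, all 3 shared.

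Interferon response genes were lower with NR as a list. None of the 20 passed over all genes in edgeR, 15 fell adjusted over the list alone, and the median log2 change was -0.33. Oas1a had a change of -0.65 ± 0.17 (SE, adjusted p = 0.345), and Ifit3, Bst2 and Irf7 changes of -0.35, -0.33 and -0.38 (adjusted p = 0.411 each). Camera called the list (adjusted p = 6.7e-18, and adjusted p = 0.031 with an estimated correlation), as did fry (0.018). Mean log2 CPM over the list was 2.26 ± 0.57 in non-running mice with neither supplement and 1.75 ± 0.16 in those with NR alone (SD, n = 8 each), 1.91 ± 0.16 with PT alone and 1.69 ± 0.17 with both. In runners the means were 2.31 ± 0.36 with neither, 2.00 ± 0.24 with NR, 2.26 ± 0.36 with PT and 2.11 ± 0.26 with both.

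Among members of the regeneration and denervation list 14 of 19 lay above 0 with NR, with Myh8 called, 3 of 19 members up adjusted over the list alone, and a median log2 change of 0.07 (camera adjusted p = 8.6e-05, adjusted p = 0.031 with an estimated correlation, fry 0.018). Beside Myh8 and Mymk, its members with the smallest p were the fetal acetylcholine receptor subunit gene Chrng at 0.92 ± 0.29 (SE, adjusted p = 0.531) and Sln at 0.51 ± 0.25 (adjusted p = 0.867). The mean log2 CPM of the list in non-runners was 2.99 ± 0.10 with both supplements and 2.59 ± 0.16 with PT alone (SD, n = 8 each), against 2.65 ± 0.30 with NR alone and 2.62 ± 0.19 with neither. In runners it was 2.47 ± 0.17 with both and 2.41 ± 0.15 with PT alone, and 2.60 ± 0.17 with NR alone and 2.42 ± 0.11 with neither. In the NAD list Nmrk2 alone was called (camera adjusted p = 0.25 for the list), with Nampt at -0.05, Nmrk1 at -0.04, Nnmt at -0.11 and Sirt1 at -0.03 (lowest adjusted p = 0.957). Ppargc1a had a log2 change of -0.01, Slc2a4 0.05, Hk2 -0.07, Pdk4 0.12 and Vegfa -0.08, and the myosins Myh7, Myh2, Myh1 and Myh4 had 0.36, -0.13, 0.10 and -0.03 (lowest adjusted p = 0.942). Of 79 nuclear-encoded OXPHOS genes 0 passed in edgeR, with a median of 0.04 (camera adjusted p = 5.1e-06, and adjusted p = 0.8 with an estimated correlation). Camera with the preset correlation also called the Schwann cell list (median -0.10, adjusted p = 8.3e-05, and adjusted p = 0.1 with an estimated correlation), the atrophy list (0.03, 0.0022, and adjusted p = 0.12 with an estimated correlation), endothelial markers (-0.04, 0.0053, and adjusted p = 0.79 with an estimated correlation), macrophage markers (-0.08, 0.031, and adjusted p = 0.8 with an estimated correlation) and fatty acid oxidation (0.03, 0.044, and adjusted p = 0.8 with an estimated correlation). The insulin signalling list had a median of 0.01 (camera adjusted p = 0.98).

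PT changed no gene past the threshold. With edgeR 0 genes and with DESeq2 0 genes were called in 32 mice against 30, and 580 had an unadjusted p below 0.05. Among the smallest p-values were those of Tfrc, the transferrin receptor gene, with a log2 change of 0.34 ± 0.08 (SE), at 237 ± 65.6 against 187 ± 39.1 CPM (SD), Elf3 at -0.55 ± 0.14, Trim35 at 0.13 ± 0.04 and Nrep at 0.15 ± 0.04 (adjusted p = 1 for each). Of the antioxidant and stilbenoid-sensing genes, Cyp1a1 had 0.30 ± 0.13, Mt2 0.36 ± 0.17, Nqo1 -0.08 ± 0.04 and Cat -0.11 ± 0.05 (camera adjusted p = 0.75 for the list). Of the always named genes, Nmrk2 had a log2 change of 0.08 under PT, Nmrk1 0.04, Nampt 0, Nnmt -0.03, Sirt1 -0.02, Ppargc1a 0.04, Pdk4 -0.30, Slc2a4 0.04, Hk2 0.04, Vegfa -0.02, Myh7 0.78, Myh2 -0.02, Myh1 0.12 and Myh4 0. Nuclear-encoded OXPHOS genes had a median of 0.07, with 78 of 79 above 0 and none called (camera adjusted p = 6.4e-25, and adjusted p = 0.71 with an estimated correlation). With the preset correlation camera called 8 lists for PT, among them the TCA cycle (0.05), glycolysis (0.04) and interferon response (-0.13) lists, and with an estimated correlation none of the 27 (adjusted p = 0.71 with an estimated correlation for each of the 3). Fry called 0 of the 27.

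The combined questions of the factorial, whether 1 factor altered the response to another, gave no called genes in edgeR. The running by NR interaction had 0 called genes and 525 at an unadjusted p below 0.05 (DESeq2 0), running by PT 0 and 511 (DESeq2 6), NR by PT 0 and 327 (DESeq2 0), and the 3-way interaction 0 and 403 (DESeq2 0). For the running by NR interaction, Nmrk2 had a log2 difference of 0.39 ± 0.28 (SE), Nmrk1 0.17 ± 0.10, Hk2 0.15 ± 0.11, Vegfa 0.11 ± 0.11, Ppargc1a 0.08 ± 0.10, Sirt1 0.08 ± 0.09, Slc2a4 0.01 ± 0.06, Nampt 0.02 ± 0.06, Nnmt 0.02 ± 0.31 and Pdk4 -0.07 ± 0.43. The myosins Myh7, Myh2, Myh1 and Myh4 had 0.47, 0.17, 0.07 and -0.02 (adjusted p = 1 for each of the 14). Over the 4 interactions, 26 of 108 list tests passed with the preset correlation, 0 with an estimated one and 0 with fry (lowest adjusted p = 0.38 with an estimated correlation). Among those 26, endothelial markers had a median running by NR difference of 0.10 (camera adjusted p = 0.0016, and adjusted p = 0.99 with an estimated correlation) and adipocyte markers a running by PT difference of -0.35 (camera adjusted p = 3.9e-08, and adjusted p = 0.38 with an estimated correlation).

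Within single supplement arms, running with NR and PT together gave the highest count, with 120 genes up and 127 down in 8 runners against 8. There Sln changed by -2.74 ± 0.48 (SE), Cdkn1a by -1.40 ± 0.24 and Stat5b by -0.32 ± 0.06, and Pde10a rose by 0.70 ± 0.13 and Rai14 by 0.53 ± 0.10. Mean Sln was 5.61 CPM in the non-runners of this arm, against 2.06 to 3.3 CPM in the other non-runner groups. In its runners Sln was at 0.878 CPM, against 0.803 to 1.74 CPM in the other runner groups. With NR alone 59 genes rose and 6 fell in 7 runners against 8, led by Sox17 at 0.74 ± 0.12, Prkch at 0.54 ± 0.10, Sdc3 at 0.46 ± 0.08, Trp53i11 at 1.07 ± 0.19 and Hspa5 at -0.29 ± 0.06. With PT alone only C1qtnf4 passed, at -0.98 ± 0.17 (8 against 8), and with neither supplement 0 genes passed in edgeR (7 against 8, 990 at an unadjusted p below 0.05, DESeq2 0). DESeq2 called 470, 157 (119 up and 38 down) and 21 genes in the other 3 arms. The count with NR alone was 26 without its library rich in ribosomal-like reads and 2 without day 4. That with NR and PT was 389 without the same library and 30 without day 4, and that with PT alone was 11 without day 2. The C1qtnf4 call ended without day 1, day 4 or day 6 and in each cohort alone, with 0 genes called in edgeR. These counts are not tests of a difference between arms, for which the interactions above had 0 calls.

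Most genes called for running in the other 3 arms together had the same sign in the arm left out. Of 1475 such genes 1348 (91.4%) had the same sign with neither supplement, as did 89.8% with NR alone, 89.5% with PT alone and 98.6% of 649 genes with both. Runners of all arms on a day shared 1 session and non-runners the other. Session differences are therefore common to the arms, and this agreement does not separate them from running. Of the 18 endothelial markers 8 were called with NR alone (median 0.42, camera adjusted p = 6e-23, and adjusted p = 0.0052 with an estimated correlation), 3 with both supplements (0.24, adjusted p = 0.23 with an estimated correlation), 0 with PT alone in edgeR (0.18, adjusted p = 0.26 with an estimated correlation) and 0 with neither (0.21, adjusted p = 0.16 with an estimated correlation). All 18 lay above 0 in each arm. With NR alone the 14 adipocyte markers also lay above 0, with a median of 0.47 and none called in edgeR (camera adjusted p = 2.7e-05, and adjusted p = 0.6 with an estimated correlation). Without the library of this arm rich in ribosomal-like reads, 5 endothelial markers were called (median 0.32, adjusted p = 0.013 with an estimated correlation), and the adipocyte median was 0.31 (adjusted p = 0.59 with an estimated correlation). With both supplements the regeneration list had 4 falls and 1 rise (adjusted p = 0.034 with an estimated correlation).

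NR in 32 non-running mice changed Nmrk2 by -1.30 ± 0.20 (SE, adjusted p = 0.000279, lower in 16 of 16 pairs) and Atcayos by 0.33 ± 0.05, and the interferon list had a median of -0.44 (adjusted p = 0.042 with an estimated correlation). The regeneration list there had a median of 0.05 (adjusted p = 0.042 with an estimated correlation, fry 0.037). In 30 runners Nmrk2 had a change of -0.91 ± 0.21 and Atcayos 0.24 ± 0.05 (adjusted p = 0.292 each). In these mice 0 genes passed for NR in edgeR (589 at an unadjusted p below 0.05, DESeq2 0), and the interferon median was -0.21 (adjusted p = 0.67 with an estimated correlation). PT gave 0 calls in non-runners (456 at an unadjusted p below 0.05, DESeq2 0) and 0 in runners (597, DESeq2 9). Both supplements against neither gave Atcayos at 0.28 ± 0.05 (adjusted p = 0.0352) and Nmrk2 at -1.03 ± 0.20 (adjusted p = 0.0455), and DESeq2 called 3 genes.

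Time of termination entered each fit as a covariate, and 0 genes were called for noon against morning in edgeR (768 at an unadjusted p below 0.05, DESeq2 1). Of 19 clock genes 4 were higher and 10 lower adjusted over the list alone, with Arntl, which encodes the clock activator BMAL1, at 0.76 ± 0.22 (SE, adjusted p = 0.468), Per2 at -0.67 ± 0.20, Hlf at -0.37 ± 0.10 and Nr1d1 at 0.34 ± 0.12. The camera p of this list was 0.041 (adjusted p = 0.29 with an estimated correlation). Within days, Arntl was higher in noon than in morning samples by 1.2 to 1.85 on 6 days, and the difference was -1.43 on day 2 and -1.88 on day 3. Without days 2 and 3, 543 genes were called for time (314 up, 229 down), 1894 for running (983 up, 911 down, 1539 shared with the full set) and 3 for NR, all 3 shared.

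**Figure D3:**
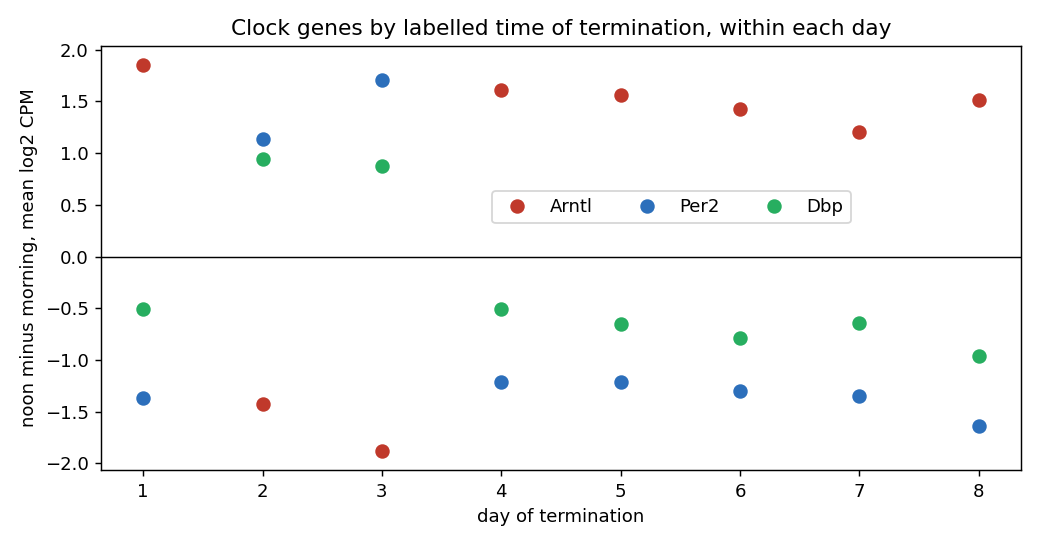
Each point is the difference in mean log2 CPM between mice labelled noon and mice labelled morning (vertical axis) for Arntl, Per2 and Dbp on each of 8 termination days (horizontal axis), from 3 or 4 mice per session. The 3 genes had the opposite sign on days 2 and 3.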

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

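Of the tests below, those of reads shared at the Nmrk2 locus, of the arm without 1 library, of each explanation for days 2 and 3 and the exchange of whole days for running and time were chosen only after the result was seen; those of RNA quality and of a shared running response were chosen before.

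The first pattern is the fall of Nmrk2 and rise of Atcayos with NR at overlapping genes. Nmrk2 reads counted as Atcayos would have lowered Atcayos as Nmrk2 fell, whereas it rose by 0.28 (SE 0.038), which argues against such spill as the cause; the residual correlation of the 2 genes over 62 animals was -0.52 (permutation p = 2e-05, the smallest possible with 100000 resamples; adjusted over 3 pairs 6e-05). Between Atcayos and Atcay the residual correlation was 0.35 (adjusted permutation p = 0.0075), as Atcay reads counted as Atcayos would give. Shared regulation could give the same, so this stays open for the rise of Atcayos. The spans of these 2 genes overlap by 4654 bases, introns included, whereas their counted lengths are 4375 and 3996 bases. The overlap of the counted bases, where reads could be shared, was not measured for any of these genes. Between Nmrk2 and Atcay the residual correlation was -0.27 (adjusted permutation p = 0.03). With RIN in the model the Nmrk2 change was -1.12 (SE 0.144), which argues against RNA quality. In each combination of running and PT, Atcayos gained less CPM with NR than Nmrk2 lost. In non-running mice without PT, Nmrk2 went from 104 ± 32.5 to 37.8 ± 10.6 CPM and Atcayos from 92 ± 6.7 to 118 ± 10.8 (SD). This argues against a transfer of reads to Atcayos as the whole of the Nmrk2 fall. Loss of Nmrk2 reads left uncounted at the overlap was not tested, and a biological response of the locus to NR stays open beside it.

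The second pattern is that calls for running ranged from 0 with neither supplement to 247 with NR and PT. A shared running response could give such counts through noise alone, and the response with neither supplement to genes called in the other arms had a slope of 0.48 (SE 0.13), below 1 but within 2 SE of the limit of 0.5 set beforehand, a limit under 1 because called genes are chosen in part for their noise; by that limit the shared response is left open. The slopes of the other arms were 0.57, 0.50 and 1.00, with SE of 0.16, 0.14 and 0.15, each against a different set of genes. Removal of the library with 29.05% ribosomal-like counts left 26 calls with NR alone, 389 with NR and PT and 0 with neither supplement. The range between arms thus remained without that library. The order of arms was also unchanged, but the library stands only in the arm with NR alone. Its removal could hardly have changed the order, so no conclusion is drawn from the order. Interactions called 0 genes in edgeR, so a supplement effect on the running response was not shown.

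The third pattern is that genes differing by time of termination ran opposite to the labels on days 2 and 3. The slopes of these days on the other 6 over 528 genes were -0.82 and -1.03, and 91.5 and 97.7% of the genes had the opposite sign, whereas the slopes of the other days lay between 0.66 and 0.86. This fits time labels exchanged between morning and noon on those days. Exchanged running labels would turn the running response of the day. Over 1777 genes called for running and not for time in the other 6 days, its slope was 0.48 (SE 0.16) on day 3. It was 0.39 (SE 0.33, 4 pairs) on day 2, where 76.5% of the genes had the same sign. Both slopes were positive, and those of the other days ran from 0.31 to 1.03. All pairs of a day compare the same sessions, so the SE leaves out the spread between sessions. An exchange would give a negative slope. On day 3 the 4 pairs ran from 0.08 to 0.80 and 85% of the genes had the same sign. With the positive slopes of every other day, this argues against an exchange on day 3. On day 2 the pairs ran from -0.28 to 1.21, so an exchange is left open there. The running effect on Arntl was -0.01 (SE 0.224), which argues against running as what set the clock genes, and no label was changed.

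A sample was singled out where its gap to the nearest other animal of its group was large against the range of the group. For normally distributed values chance flags about 1 in 20 sets, a rate that need not hold for skewed levels. Of 152 sets, each 1 measure in 1 group, 17 held such a sample. Ribosomal-like reads took 29.05% of counts in replicate 1 of running mice with NR alone (others 0.20 to 0.49), 2.74% in replicate 2 of non-running mice with both supplements, 2.52% in replicate 7 of non-running mice with neither and 0.63% in replicate 5 of running mice with both. Mitochondrially encoded genes took 12.46% in replicate 5 of non-running mice with both (others 9.03 to 10.57). Myh7 stood at 25.4 CPM in replicate 6 of running mice with neither (others 0.338 to 2.37), where Myh1 stood at 8010 CPM (others 2970 to 5000). Myh7 was also high at 5.9 CPM in replicate 6 of non-running mice with PT, 4.78 in replicate 2 of running mice with NR and 3.48 in replicate 5 of running mice with PT, where Pdk4 stood at 1610 CPM (others 95.2 to 585). Myh8 stood at 7.18 CPM in replicate 2 of non-running mice with NR (others 3.81 to 4.81) and at 5.65 CPM in replicate 3 of non-running mice with PT (others 3.22 to 4.17). Slc2a4 was at 516 CPM in replicate 3 of running mice with PT, Ppargc1a at 21.7 CPM in replicate 4 of non-running mice with both, Nmrk1 at 4.89 CPM in replicate 1 and Myh4 at 49200 CPM in replicate 8 of non-running mice with NR.

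Regroupings of the samples, the true labels included, were judged for each result alone, without allowance for the number of results. No other regrouping reached the running calls (2035, highest other 1040, 1 of 75 as large), which argues against chance for that count. Running with NR alone also had its highest count under the true labels (65, highest other 52, 1 of 75). For running with NR alone, however, other settings gave counts below 52, such as 26 without 1 library and 2 without day 4. Chance is therefore left open for this arm. The calls for NR (3, highest other 0, 1 of 40) were also reached by no other regrouping. This argues against chance for that count taken alone, and 1 of 40 is the smallest share that 40 regroupings can give. NR in non-running mice (2, highest other 1, 1 of 40) is not separate evidence, since its 2 genes, Nmrk2 and Atcayos, are among the 3. No other regrouping matched the interferon median under NR (-0.33, highest other 0.26, 1 of 40), but chance is left open there. The list was 1 of 2 called among 27 with an estimated correlation in these same samples, and only those 2 were regrouped. Chance is also left open for 2 results whose side of the 0.05 limit changed with the draws. These are running with NR and PT (247, highest other 330; 3 of 75, 3 of the first 40 and 2 of 40 with another seed) and the endothelial median (0.25, highest other -0.26; 2 of 75, 1 of the first 40 and 2 of 40 with another seed). Chance cannot be excluded for running with PT alone (1, highest other 1; 4 of 75), the median of nuclear-encoded OXPHOS genes under running (0.14, highest other 0.18; 4 of 75), NR and PT together against neither (2, highest other 50; 2 of 40) or the regeneration median under NR (0.07, highest other 0.12; 2 of 40). A count of 0 is matched by every regrouping whatever the data, so such shares carry no information and only the highest others are of use. The share was 75 of 75 for running with neither supplement (highest other 8). It was 40 of 40 for PT (0), running by NR (3), running by PT (0), NR by PT (0) and the 3-way interaction (1). The same held for NR in running mice (3), PT in non-running mice (9), PT in running mice (24) and noon (778). The 778 came from exchange of days 2 and 3. With single animals exchanged within days, 40 regroupings gave highest others of 553 for running, 2 for running with NR alone, 55 for running with NR and PT, -0.15 for the endothelial median and 0.14 for the OXPHOS median.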

How the results depend on the processing

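Removal of days 2 and 3, of 1 or 4 libraries rich in ribosomal-like reads, and the fits by session (the morning or noon of 1 day) were chosen only after the results were seen; the other settings were chosen before. Across 26 settings, counts of calls stayed within 1.5 times the value in the report in 325 cases and moved in 77. The 325 include counts of 0 that stayed 0, as for PT in each setting, so they overstate how stable the counts above 0 were. Named genes kept direction and side of the threshold in 4641 cases and lists in 425. With the same direction, named genes lost the call in 459 cases and gained it in 114, and lists lost it in 54. Direction turned in 118 cases, 111 of them for genes and 7 for lists, and none of those genes had been called. Where days, cohorts or libraries were left out, fewer samples were fitted; elsewhere the cause was not tested. At a median of 16.1 M counts per library, genes with low counts were not tested. Session as a fixed block gives no value for running, its arms or time, since it contains both factors.

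For running, 1333 genes were called with no filter on low counts (more genes tested), 623 in cohort 1 alone, 63 in cohort 2 alone and 1275 on counts summed per session. With a day or the 1 library left out, the count ran from 1036 to 2391 (running), 2 to 99 (running with NR alone), 0 to 11 (running with PT alone), 30 to 448 (running with NR and PT), 0 to 2 (PT in non-running mice), 0 to 2 (NR and PT together against neither) and 0 to 206 (noon against morning). For running with NR alone the count was 157 with DESeq2, 29 with no filter, 39 with pool added, 0 in cohort 1, 0 in cohort 2, 32 without days 2 and 3 and 34 with session as a random block. For running with NR and PT it was 470 with DESeq2, 86 with no filter, 163 with pool added, 52 in cohort 1, 0 in cohort 2 and 102 without days 2 and 3. For running with PT alone it was 21 with DESeq2, 0 in cohort 1 and 0 in cohort 2.

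For NR the count was 1 in cohort 1 and 0 in cohort 2, and for NR in non-running mice 4 with DESeq2, 0 in cohort 1, 0 in cohort 2 and 1 without days 2 and 3. DESeq2 called 6 genes for running by PT, 9 for PT in running mice and 1 for noon. PT in running mice gave 8 calls with no covariates and 1 in cohort 1, and PT in non-running mice 2 with pool added. NR and PT together against neither gave 0 with no filter, 1 with no covariates, 1 with cohort in place of day, 1 with pool added, 0 in cohort 1, 0 in cohort 2, 0 with 4 libraries removed, 0 without days 2 and 3 and 1 with session as a fixed block. Noon against morning gave 254 in cohort 2 and 543 without days 2 and 3.

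The replicate number as a block in place of day gave 35 calls for running with NR alone, 1 for NR and PT together against neither and 1976 for running, and its insulin list p under NR was 1. The labels give no pairing by number. Deviations of animals with the same number had a mean correlation of 0.008 (lowest -0.41), and 15 of 62 libraries correlated best with their own number, so the numbers were not used as pairs. The block changed no other count by more than 1.5 times.

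None of the genes whose direction turned had been called, and their log2 changes in the report reached 1.54 in size (Myl3, running). In cohort 1 these were, for running, Nmrk2 0.09 and Myl3 -0.05; for NR, Ppargc1a 0.01, Hk2 0.04, Myh2 0.09 and Myh4 0.04; for PT, Myh4 0; for running by NR, Nnmt -0.21 and Pdk4 0.35; for noon, Hlf 0.01, Per2 0.11 and Arntl -0.07. In cohort 2 they were, for running, Nmrk1 0.01, Nnmt -0.10 and Sirt1 0.02, and for NR, Nnmt 0.22, Pdk4 -0.12, Myh7 -0.25 and Myh1 -0.11. In cohort 2 for PT they were Nmrk1 -0.01, Nmrk2 -0.18, Nampt 0.01, Nnmt 0.07, Sirt1 0, Myh2 0.12 and Vegfa 0.05. In cohort 2 for running by NR they were Sirt1 -0.01, Ppargc1a -0.01, Myh7 -0.98, Myh2 -0.97, Myh1 -0.40, Myh4 0.15 and Vegfa -0.09.

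Without days 2 and 3 they were, for running, Nnmt -0.16, Sirt1 0 and Hbb-bs 0; for NR, Sirt1 0.03 and Ppargc1a 0.02; for PT, Nnmt 0.08, Myh2 0.24, Myh4 -0.01 and Vegfa 0.03. For running by NR they were Nampt 0, Ppargc1a -0.01, Slc2a4 -0.01, Myh2 -0.22, Myh1 -0.12 and Myh4 0.01. With pool added they were Sirt1 0 (running), Myh2 0 and Myh4 -0.01 (PT), and Pdk4 0.19 and Slc2a4 -0.01 (running by NR). With no covariates they were Nampt 0 and Myh2 0.01 (PT), and with cohort in place of day Nampt 0 (PT). With 4 libraries removed they were Nnmt -0.05 (running), Nnmt 0.06 and Myh4 -0.01 (PT). With RIN added they were Nnmt 0 and Sirt1 0, and with counts summed per session Nnmt -0.01, all for running.

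With days or the 1 library left out, uncalled genes ranged as follows. For running, Nmrk1 ran from -0.05 to 0.01, Nmrk2 from -0.14 to 0.03, Nnmt from -0.09 to 0.09 and Sirt1 from -0.03 to 0.02. For NR, Nnmt ran from -0.25 to 0.01, Sirt1 from -0.06 to 0.01, Ppargc1a from -0.03 to 0 and Myh7 from -0.09 to 0.84. For PT, Nmrk2 ran from -0.03 to 0.20, Nampt from -0.03 to 0.01, Nnmt from -0.10 to 0.10, Myh2 from -0.20 to 0.15, Myh4 from -0.02 to 0.04 and Vegfa from -0.05 to 0.02. For running by NR, Nampt ran from -0.02 to 0.05, Nnmt from -0.15 to 0.24, Ppargc1a from -0.04 to 0.14, Pdk4 from -0.34 to 0.29, Slc2a4 from -0.03 to 0.03 and Vegfa from 0 to 0.14. For running by NR, Myh7 ran from -0.15 to 1.49, Myh2 from -0.25 to 0.44, Myh1 from -0.18 to 0.20 and Myh4 from -0.10 to 0.06.

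The nuclear-encoded OXPHOS list lost its camera call with an estimated correlation for running (adjusted p = 0.29), NR (0.8) and PT (0.71), since the estimate allows its members to vary together. For running by NR its direction turned without the 1 library (adjusted p = 0.014) and with 4 libraries removed (0.015). The insulin list under NR turned direction, uncalled in each fit, with adjusted p of 0.95 with no covariates, 0.91 with cohort in place of day, 0.4 with 4 libraries removed and 0.58 without the 1 library.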

Other observations

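The tests of the endothelial list in this part were set aside as a weighed pattern after their values were seen. The mean of the 18 endothelial markers rose with running by 0.27 ± 0.037 on the log2 scale (SE), by 0.27 ± 0.038 with RIN in the model, and by 0.37 ± 0.052 relative to the mean of Schwann cell and nerve markers. No count of cells or capillaries was part of the data.

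For running, Sln and Cdkn1a had log2 changes of -1.93 and -0.57 with neither supplement, -0.85 and -0.31 with NR alone and -0.67 and -0.36 with PT alone. None of these was called (lowest edgeR adjusted p = 0.434). With both supplements the changes were -2.74 and -1.40, called for both genes (adjusted p = 0.00424 each), and neither gene had a called interaction.

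With each library left out in turn, the interferon median under NR ran from -0.35 to -0.27 and the regeneration median from 0.05 to 0.09.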
